A study of Mus musculus with 6 samples.

How the data were processed

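RNA of 6 subcutaneous MAC-16 tumours in NSG mice was hybridised to 6 Affymetrix mouse ST 2.0 arrays, 3 tumours given vehicle and 3 given PNB-028. Per the labels' protocols, treatment began at a tumour volume of 100 to 200 mm3, RNA was diluted to 100 ng/µl, and samples with an RNA integrity number over 7 were used. The labels name Transcriptome Analysis Console and Ingenuity Pathway Analysis for the authors' own analysis. Groups and replicate numbers were taken from the sample titles. The labels count 3 tumours per group, and limma's p-values for genes set each difference against the spread between these tumours. That each tumour came from a mouse of its own is not spelled out.

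The deposited values were log2 signals, 1 per probe set and array, with 2 decimals. The background correction, summarization and normalization behind them are not given in the sources used here. Columns had nearly equal distributions without being identical. The scale was read from the range of the values, 2.19 to 15.22. Gene symbols came from the platform annotation: 233753 of the 269751 probe sets had 1 symbol, 5106 had several and 30892 had none here, and only those with 1 symbol were named. The 23152 symbols had a median of 8 probe sets each, so most probe sets measure a part of a gene. Symbols were updated through RefSeq names of GRCm38.p6, by which 2247 symbols have another current name and 30 have no unique one. No coordinates are given, because the build of the array annotation is not given in the sources used here.

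A probe set was kept if its mean over the 6 arrays lay above the 40th percentile of all probe sets (6.68), and the one with the highest mean stood for its gene, which left 17732 genes. These were fitted in limma 3.58.1 (lmFit and eBayes, R 4.3.3) as PNB-028 against vehicle with no covariate, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Gene lists were tested with camera (preset correlation 0.01), with at least 3 tested members, and adjusted over the 41 lists. With the preset, camera sets a list's genes against the other genes. Those p-values do not measure how far a list as a whole varies between tumours. Camera with an estimated correlation and fry stood beside it. Of 874 list members, 819 matched the annotation, 8 of them through a synonym. A tumour's list score is the mean over the list's genes of the value minus that gene's mean over the 6 tumours. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

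The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names up to 12 called genes per direction whose groups do not overlap; where fewer pass, up to 6 per direction of smallest p with at least a 1.5-fold difference and no overlap, described by values only. It also names Cckar, Cckbr, Cck and Gast, the 4 members of smallest p of each called list and up to 2 of each other list named. Predicted genes, clone names, small RNAs and olfactory or vomeronasal receptors were not named under the first parts of the rule.

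The gene and list tests were tested on simulated data, 20 rounds over the 17732 genes with 200 genes changed. Limma called 5.1% of genes changed by 0.5 on the log2 scale, 55% of those changed by 1, 87.5% of those changed by 2 and 96.9% of those changed by 3. It also called a mean of 6.05 unchanged genes per round. The larger changes ease the adjusted threshold, so these shares are too high where few genes change. Each gene's estimated residual SD was taken as its true SD, so genes with an SD low by chance were called more easily. The shares are therefore not the power of this design. A list shifted by 0.5 was called in 100% of rounds. Simulated genes varied independently, so this share does not cover lists whose genes vary together between tumours.

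Alternatives were no filter or a stricter one (60th percentile), all probe sets, the mean of a gene's probe sets, median centring, quantile normalization, other variance models, array weights, the replicate number as a block, each array left out, and other thresholds. Added after the data were seen were the interquartile width of each array as a covariate and leaving out isolated low probe sets. Probe sets without a single symbol or below the filter were tested apart from the genes: 0 of 30892, 5106 and 84588 passed in limma, with 1138, 183 and 6040 at an unadjusted p under 0.05.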

Results

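RNA from 6 tumours of MAC-16, a mouse colon cancer line known to cause weight loss in its host, was measured on 6 mouse whole-transcript arrays. The cells had been implanted under the skin of NSG mice, a strain without mature lymphocytes, so tumour and host transcripts are both of mouse and are read by the same probe sets. The vehicle group (20% DMSO and 80% PEG-300) held 3 tumours, and the PNB-028 group, dosed orally at 50 mg/kg/day, held 3. Tumours were taken 6 hours after the last dose, when they had reached 1500 mm3 or the mouse had lost over 20% of its body weight. The value table held 269751 probe sets on the log2 scale, with array medians of 7.43, 7.46 and 7.42 for vehicle replicates 1 to 3 and 7.46, 7.44 and 7.40 for PNB-028 replicates 1 to 3. How those values were normalized is not given in the sources used here. Pairs of arrays correlated across probe sets at 0.969 to 0.976 within vehicle, 0.967 to 0.971 within PNB-028 and 0.964 to 0.974 between the groups. Probe sets are not independent replicates, and these correlations only describe the arrays. No pair of arrays was a duplicate. The number of arrays, 3 per group, limits the precision of every value given here.

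The question put to the arrays was which genes of the tumour differ after PNB-028. No gene passed the test across 17732 genes. The genes with the smallest p included, on the higher side, Has2, which makes hyaluronan, at 0.79 (95% confidence interval 0.43 to 1.15, log2), Nrg1, a ligand of ERBB receptors, at 0.69 (0.37 to 1.02), and Mug1, a secreted protease inhibitor, at 0.97 (0.59 to 1.36). Gp49a, now named Lilr4b, differed by 1.75 (0.94 to 2.56), Slfn8 by 0.79 and A1bg by 0.85. On the lower side were Tox3 at -0.95 (-1.32 to -0.58), Pik3c2g, a class II phosphoinositide kinase, at -0.91 (-1.22 to -0.60), Rragd, a GTPase that acts on mTORC1, at -1.06, Alox15, a lipoxygenase, at -0.69, Zp4-ps at -0.77 and Mertk, a receptor for the clearance of dying cells, at -0.78. The rule for naming these 12 genes required a 1.5-fold difference and 3 PNB-028 values on one side of the 3 vehicle values. That separation is therefore no result of its own. Each of the 12 genes had an adjusted p of 0.938 in limma. The probe sets of 1 gene did not always go together: for Tox3 all 9 tested probe sets were lower, for Mug1 all 10 were higher, and for Mertk 6 were higher and 6 lower, with a mean of 0.07 over them. Means over all probe sets were also smaller for Nrg1 (0.15, 1 of 4 lower), Has2 (0.43), Pik3c2g (-0.45, 1 of 9 higher) and Alox15 (-0.26, 3 of 11 higher), and larger for Mug1 (1.47). A1bg, Slfn8, Rragd and Zp4-ps rested on 1 tested probe set each. In 1 group the mean lay below the filter of 6.68 for Slfn8 (6.62 with vehicle), Rragd (6.45 with PNB-028) and Zp4-ps (6.48 with PNB-028).

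**Figure D1:**
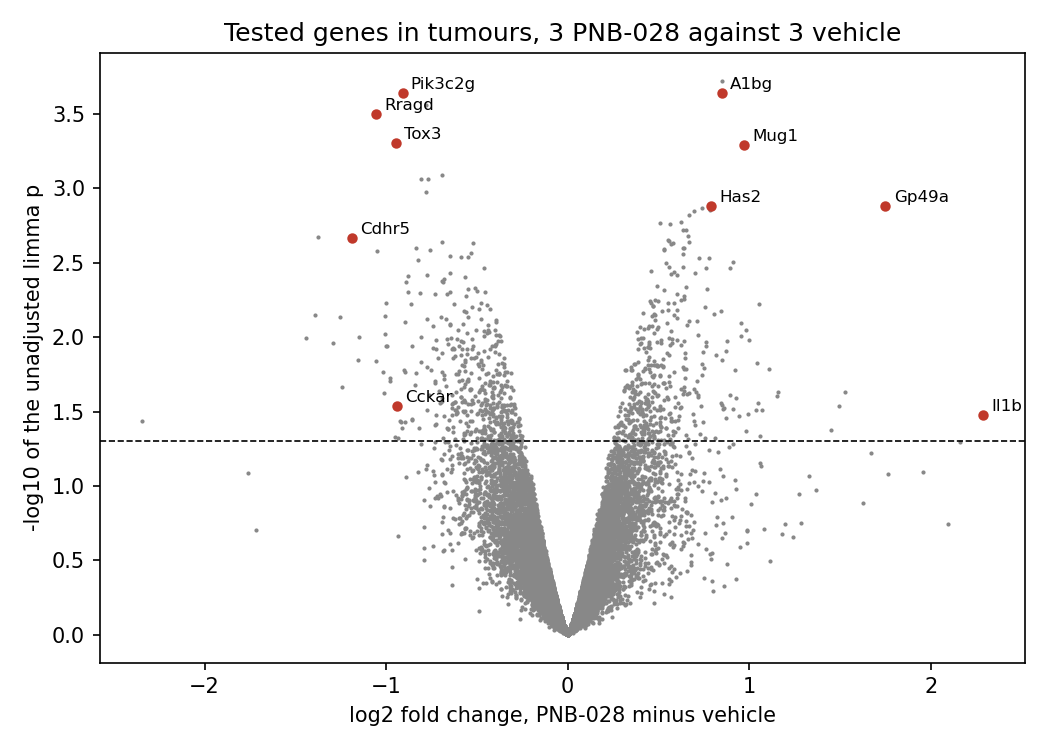
Each grey point is 1 of 17732 tested genes; the x axis is the log2 fold change of PNB-028 (n = 3) minus vehicle (n = 3), the y axis the negative log10 of the unadjusted limma p, and the dashed line lies at an unadjusted p of 0.05. The genes labelled in red are 10 of those named in the text; 895 genes lie above the line and none passed after adjustment.

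In limma with Benjamini-Hochberg adjustment, 0 of 17732 genes passed at 0.05, and the smallest adjusted p was 0.938. At an unadjusted p under 0.05 there were 895 genes, 427 higher and 468 lower, which is 5.05% of those tested, where chance gives 5% (886.6 genes). The 3 PNB-028 values lay wholly above or below the 3 vehicle values for 1744 genes, or 9.84%, where chance gives 10%. Adding a 2-fold criterion to the unadjusted p left 33 genes, 14 higher and 19 lower, and a 1.5-fold criterion left 262. Linear models without moderation also called 0 genes. The median log2 fold change of all tested genes was -0.01. The array medians as deposited differed by -0.003 between the groups (PNB-028 minus vehicle, two-sided exact permutation p = 1), and the medians over the tested genes by 0.02 (exact permutation p = 0.7); 3 arrays against 3 allow no p under 0.1. The median half-width of a gene's unadjusted 95% interval was 0.37. In simulated data of this design limma called 5.1% of genes changed by 0.5 and 55% of those changed by 1. Those shares apply where 200 genes changed, some of them by 2 or 3, which eases the adjusted threshold. They also take each gene's estimated residual SD as its true SD, so they are not the power of this design. Where no other gene passes, a gene with the median standard error would need a difference of 2.1 to pass. Leaving out PNB-028 replicate 3 gave 1 gene, Nr1h3, the nuclear receptor LXR-alpha, at -3.55 (adjusted p = 0.0195 in limma); with another array left out, the smallest adjusted p of any gene was 0.209 to 0.999. It was chosen after its values were seen, and the other tested probe sets of Nr1h3 differed by a median of -0.14 between PNB-028 replicates 1 and 2 and the other arrays.

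Transcripts of the cholecystokinin and gastrin system were measured because PNB-028 is known, as background, as a compound directed at the cholecystokinin A receptor. The transcript of that receptor, Cckar (probe set 17448141), averaged 8.71 ± 0.59 with vehicle and 7.77 ± 0.48 with PNB-028 (log2, SD, n = 3 each), a difference of -0.94 with a 95% interval of -1.75 to -0.13. All 4 tested probe sets of Cckar were lower, with a mean of -1.05. The groups overlapped, since vehicle replicate 2 read 8.03 and PNB-028 replicate 3 read 8.32. Cckbr, the gastrin receptor, differed by -0.17 (-0.65 to 0.31), Gast, which encodes gastrin, by -0.16 (-0.71 to 0.39), and Cck, which encodes cholecystokinin, by 0.01 (-0.55 to 0.57). Cckar ran from -0.74 without vehicle replicate 3 to -1.28 without vehicle replicate 2. All 4 genes read higher in vehicle replicates 1 and 3 and PNB-028 replicate 3 than in the other 3 arrays, a split other than treatment. Cckar read 8.98, 9.11 and 8.32 in the first set, and 8.03, 7.49 and 7.49 in the second. Its difference between the groups cannot be told apart from that split. The differences of Cckbr, Gast and Cck moved with single arrays. Cckbr ran from -0.027 without vehicle replicate 1 to -0.40 without vehicle replicate 2, Gast from -0.025 to -0.40 without the same arrays, and Cck from -0.21 without PNB-028 replicate 3 to 0.22 without PNB-028 replicate 1, and it was also lower, at -0.13, without vehicle replicate 2. Cckbr rested on 1 tested probe set, with means of 6.90 with vehicle and 6.73 with PNB-028, close to the filter of 6.68. Little can be read from its difference. None of the 4 passed in limma, where Cckar had an adjusted p of 0.938, and 0 passed adjusted over the list alone, where the smallest was 0.116.

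**Figure D2:**
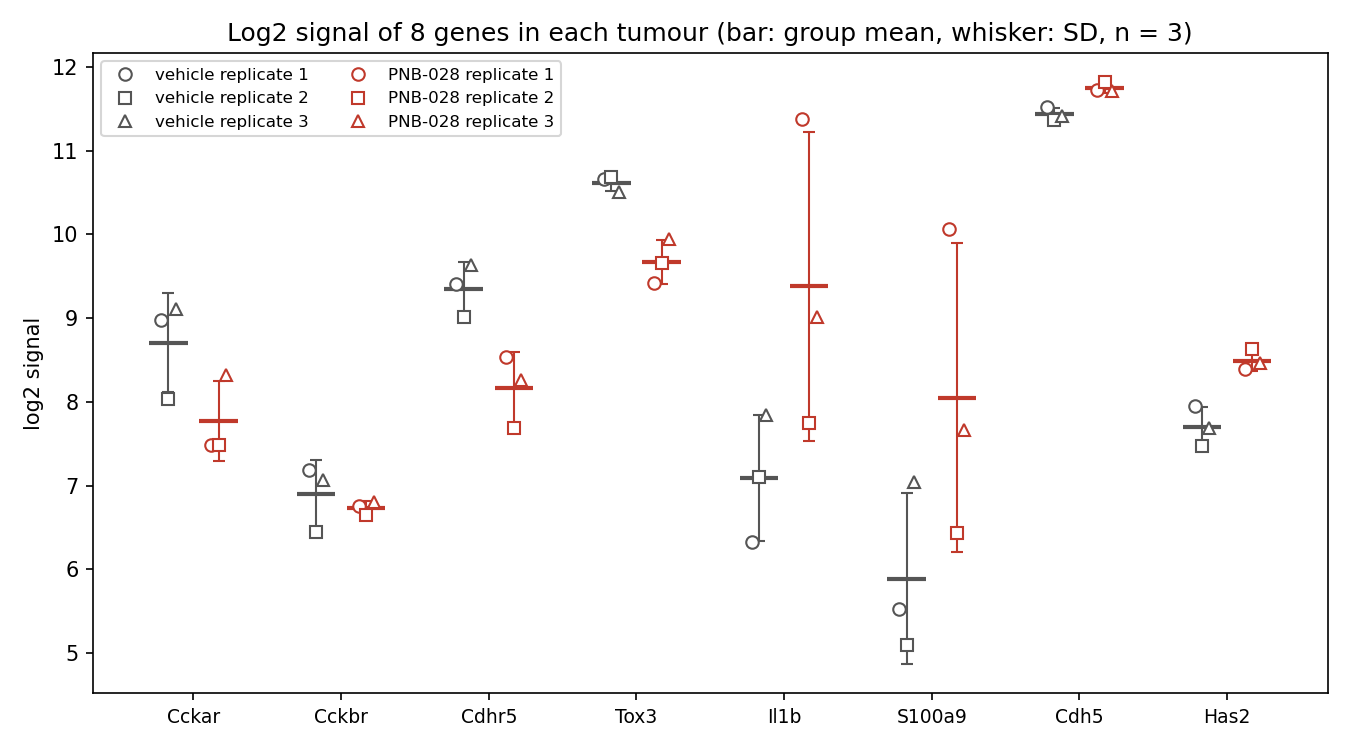
Log2 signal of 8 genes in each of the 6 tumours, vehicle in grey and PNB-028 in red, with a symbol per replicate, the group mean as a bar and the SD as a whisker (n = 3). Cckar was 7.49 in PNB-028 replicates 1 and 2 and 8.32 in replicate 3, and the high Il1b and S100a9 values of 11.38 and 10.06 belong to PNB-028 replicate 1.

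Of 41 gene lists fixed before the data were examined, 3 were called higher with PNB-028 by camera with a preset correlation and 0 lower. With an estimated correlation camera called 0 lists (adjusted p = 0.987 for each of the 3), and fry called 0 (adjusted p = 0.98 for each). With 1 array left out the count of called lists was 2 without PNB-028 replicate 1, 12 without vehicle replicate 2, 11 without PNB-028 replicate 2, and 5 without vehicle replicate 1 or PNB-028 replicate 3. The list of NF-kappaB targets and inflammatory chemokines shifted by a mean of 0.61 over 26 members, 22 of them higher (camera, adjusted p = 6.95e-05 with the preset and 0.987 with an estimated correlation). Its members with the smallest p were Icam1, an adhesion molecule, at 0.58 ± 0.15 (SE), the cytokines Il1b at 2.29 ± 0.87 and Tnf at 0.94 ± 0.36, and Nfkbiz at 0.57 ± 0.22. All 9 probe sets of Icam1 were higher, with a mean of 0.33. Neutrophil markers shifted by 0.57 over 17 members, 16 of them higher (camera, adjusted p = 0.000178 with the preset and 0.987 with an estimated correlation), among them the cytokine receptor Csf3r at 1.16 ± 0.40, the chemokine receptor Cxcr2 at 1.07 ± 0.40, the granule protein S100a9 at 2.16 ± 0.92 and Il1r2 at 0.46 ± 0.22, or 0.31 over its probe sets and 0.21 without vehicle replicate 3. Both shifts lay mainly in 1 tumour: the NF-kappaB score was 1.12 in PNB-028 replicate 1, -0.34 in replicate 2 and 0.13 in replicate 3, against -0.32, -0.38 and -0.21 in the vehicle tumours. For neutrophil markers the scores were 0.95, -0.30 and 0.20 with PNB-028 and -0.35, -0.41 and -0.10 with vehicle. Without PNB-028 replicate 1 the calls were lost, with shifts of 0.20 (camera, adjusted p = 0.356) for the NF-kappaB list and 0.23 (adjusted p = 0.183) for neutrophil markers, and with Il1b at 1.29, Tnf at 0.51, Nfkbiz at 0.33, Csf3r at 0.70, Cxcr2 at 0.68 and S100a9 at 1.16. Icam1 at 0.58 and Il1r2 at 0.43 hardly moved.

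Endothelial markers, the other list called, shifted by a mean of 0.24 over 22 members, 20 of them higher (camera, adjusted p = 0.000149 with the preset and 0.987 with an estimated correlation). Examples were Cdh5, which encodes VE-cadherin, at 0.32 ± 0.11 (SE), the receptor Tie1 at 0.48 ± 0.17, Emcn, which encodes endomucin, at 0.34 ± 0.14, and the peptide Apln at 0.85 ± 0.31. The 3 PNB-028 tumours scored 0.09, 0.05 and 0.22, all above the vehicle tumours at -0.04, -0.12 and -0.20 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). The list was picked by its call in these same values, so the separation is no support of its own. With the preset correlation the call held with each array left out, at shifts of 0.19 to 0.28 (camera, adjusted p from 4.33e-05 to 0.0271). Tie1 rested on probe sets that went both ways, 8 higher and 5 lower with a mean of 0.06, while all 10 of Cdh5 and all 11 of Emcn were higher. Apln was at 0.53 without vehicle replicate 3 and Emcn at 0.22 without PNB-028 replicate 3. In all 41 lists, 0 members passed in limma over all genes, and 0 members of these 3 lists passed adjusted over the list alone.

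**Figure D3:**
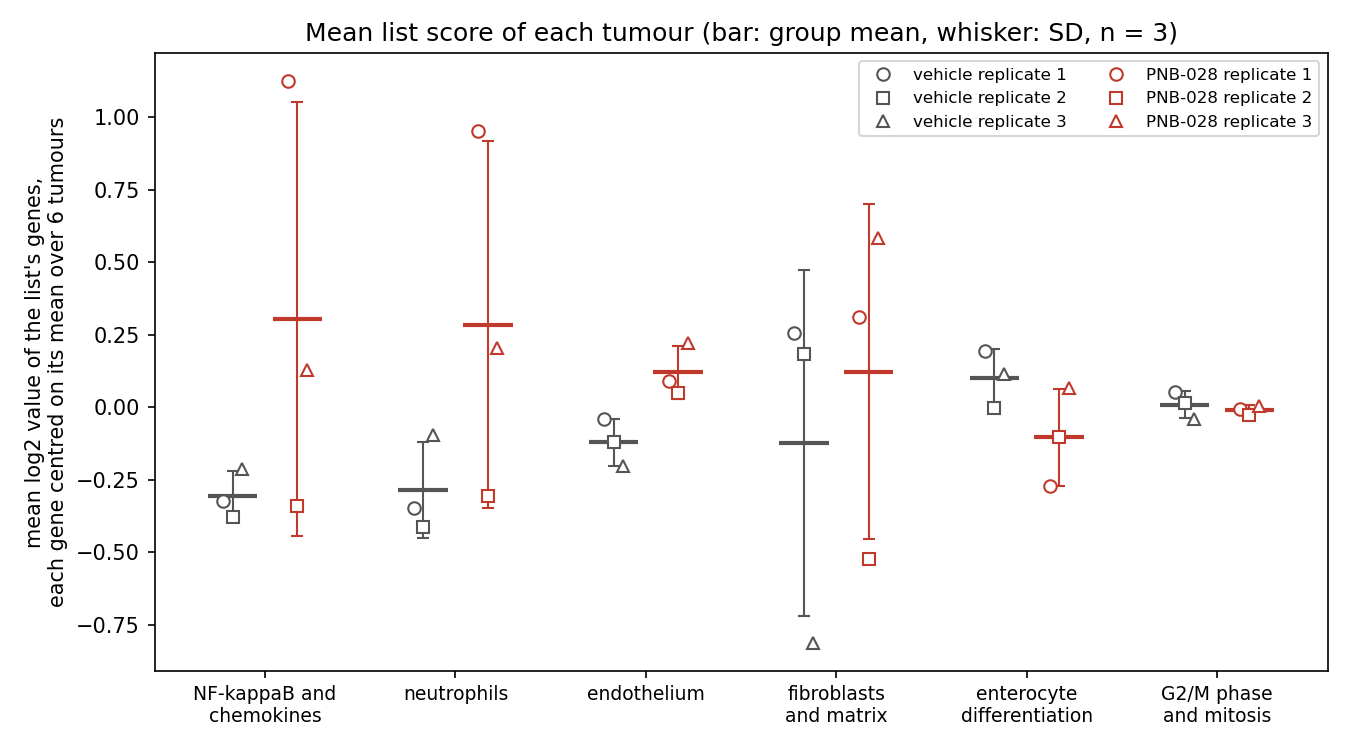
Mean score of 6 gene lists in each tumour, in log2 units after each gene was centred on its mean over the 6 tumours; vehicle is grey, PNB-028 red, the bar is the group mean and the whisker the SD (n = 3). PNB-028 replicate 1 stands at 1.12 for the NF-kappaB list and 0.95 for neutrophil markers, while the endothelial scores separate the groups by a smaller distance.

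Markers of the tumour's own epithelium were lower on average without passing in the main setting. Enterocyte and secretory scores followed a split other than treatment. In vehicle replicates 1 and 3 and PNB-028 replicate 3 the enterocyte scores were 0.196, 0.115 and 0.065, and the secretory scores 0.091, 0.269 and 0.177. In vehicle replicate 2 and PNB-028 replicates 1 and 2 they were -0.003, -0.27 and -0.103, and -0.123, -0.24 and -0.174. Junction and keratin scores did not separate this way. Enterocyte differentiation genes averaged -0.20 over 17 members, 12 of them lower (camera, adjusted p = 0.129), and Cdhr5, a protein of the microvillar brush border, differed by -1.19 ± 0.25 (SE), with all 13 tested probe sets lower. Cdhr5 was the 1 member of any list that passed adjusted over the list alone (0.0369 in limma); over all genes its adjusted p was 0.938. Cdx2, an intestinal transcription factor, differed by -0.42 ± 0.20, or -0.27 over its 3 probe sets and -0.23 without PNB-028 replicate 2. The enterocyte mean was -0.12 without PNB-028 replicate 1. With the preset correlation the list passed at -0.34 with all probe sets tested (camera, adjusted p = 1.32e-12, where probe sets of 1 gene are not independent), at -0.20 with the mean of a gene's probe sets (0.0401) and at -0.25 with the stricter filter (0.0492); with an estimated correlation its adjusted p was 0.987. Secretory cell genes averaged -0.16 over 18 members (camera, adjusted p = 0.11), with Fcgbp, a mucus protein, at -0.39 and Chga, a granule protein of endocrine cells, at -0.43, or -0.27 over its 3 probe sets, 1 of them higher. Fcgbp was at -0.24 without vehicle replicate 3. The mean of the secretory list was -0.06 without vehicle replicate 3 and -0.08 without PNB-028 replicate 1, and passed at -0.26 without vehicle replicate 2 (camera, adjusted p = 0.0288) and -0.29 without PNB-028 replicate 3 (0.0103), and at -0.18 with all probe sets (0.000224). With an estimated correlation over all 6 arrays the adjusted p of the secretory list was 0.987 in camera. Junction and keratin genes averaged -0.09, with 18 of 24 lower (adjusted p = 0.11 in camera), among them Krt7 at -0.29 and the plakin Evpl at -0.39. Means over all probe sets were -0.03 for Krt7, with 3 of 9 higher, and -0.19 for Evpl. The mean of this list ran from -0.12 to -0.04 over the 20 alternatives, and it was -0.05 without PNB-028 replicate 3. It passed in 2 of them, with the stricter filter (camera, adjusted p = 0.0492) and at -0.12 without PNB-028 replicate 2 (0.0166), but not with an estimated correlation (adjusted p = 0.987).

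Cholesterol synthesis genes were lower in 15 of 17 members, with a mean of -0.11 (camera, adjusted p = 0.0635 with the preset and 0.987 with an estimated correlation). The mean lay between -0.13 and -0.09 in all 20 alternatives, and with the preset correlation 7 of them passed, among them the stricter filter (camera, adjusted p = 0.0275), the mean of a gene's probe sets (0.014) and all probe sets (0.000578). Hmgcs1, an early enzyme of the pathway, differed by -0.32 ± 0.13 (SE), with all 10 probe sets lower, and Mvk, mevalonate kinase, by 0.34 ± 0.12, with a mean of 0.11 over its probe sets. This was the only list of the 41 that passed fry's test for change in either direction (adjusted p = 9.86e-05), while fry's directional adjusted p was 0.705 and camera's adjusted p = 0.987 with an estimated correlation. The acute phase and STAT3 list averaged 0.36 over 18 members (camera, adjusted p = 0.0609), with the receptor Osmr at 0.29 and haptoglobin, Hp, at 1.28 ± 0.86, or 0.78 over its probe sets. Without PNB-028 replicate 1, Osmr was at 0.17 and Hp at 0.53, and Hp was at 2.28 without PNB-028 replicate 2. The list too depended on single tumours, with a mean of 0.09 without PNB-028 replicate 1 (camera, adjusted p = 0.874), and passed at 0.43 without vehicle replicate 2 (0.0192) and 0.68 without PNB-028 replicate 2 (1.93e-07), and also with all probe sets (3.66e-07), their mean (0.00147), the stricter filter (0.0391), quantile normalization (0.0499) and trend and robust (0.035). With an estimated correlation over all 6 arrays its adjusted p was 0.987 in camera. Mesenchymal transition genes averaged 0.22 (camera, adjusted p = 0.0976), although Itga5, an integrin, was at 0.51, or 0.31 over its 18 probe sets, and the transcription factor Twist1 at -0.73. The mean of the list was 0.07 without vehicle replicate 3 (camera, adjusted p = 0.55) and 0.11 without PNB-028 replicate 3, and passed at 0.39 without PNB-028 replicate 2 (0.000304), at 0.30 without vehicle replicate 1 (0.0368) or 2 (0.044), and with all probe sets (0.37, 2.48e-09), their mean (0.0357) and the stricter filter (0.0371). With an estimated correlation over all 6 arrays its adjusted p was 0.987 in camera.

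Other lists that fit a cachexia-inducing tumour did not pass in the main setting either. Secreted factors associated with cachexia averaged 0.20, with 11 of 19 higher (camera, adjusted p = 0.196), and Inhba, which encodes an activin subunit, differed by 0.47 ± 0.17 (SE), or 0.73 over its 3 probe sets. With all probe sets this list passed at 0.31 (camera, adjusted p = 0.00032); with an estimated correlation its adjusted p was 0.987. Mitotic genes averaged -0.02 over 27 members, 13 higher and 14 lower (camera, adjusted p = 0.934), and turned to 0.00321 without vehicle replicate 1, with the proliferation marker Mki67 at -0.41 ± 0.14, or -0.17 over its 16 probe sets, and Cdca8 at -0.23. Hypoxia and glycolysis genes averaged 0.07 (camera, adjusted p = 0.508), with Car9 at 0.63 ± 0.38 and Pfkp at 0.31. Car9 ran from 0.32 without vehicle replicate 3 to 0.98 without PNB-028 replicate 3, and Pfkp from 0.17 without vehicle replicate 1 to 0.47 without vehicle replicate 2. The list's mean turned to -0.09 without PNB-028 replicate 2 and passed at 0.24 without PNB-028 replicate 3 (camera, adjusted p = 2.91e-05) and at 0.08 with all probe sets (0.0223). With an estimated correlation over all 6 arrays its adjusted p was 0.987 in camera.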

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

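The array width covariate and leaving out isolated low probe sets were chosen after seeing the data. The count of 0 genes in limma held under every alternative of the fit except without PNB-028 replicate 3 (leave-one-out range 0 to 1); criteria of unadjusted p with 2-fold gave 33 genes and with 1.5-fold 262. Genes at unadjusted p under 0.05 numbered 628 to 1334 with 1 value per gene and 8440 of 161847 with all probe sets; the leave-one-out range was 699 to 1267. Called lists, 3 in the main setting, were 9 with the stricter filter, 18 with all probe sets, 10 with the mean of a gene's probe sets, 5 with trend and robust, 0 with an estimated correlation, 0 with fry and 2 to 12 with 1 array left out (5 without vehicle replicate 1, 12 without vehicle replicate 2, 11 without PNB-028 replicate 2, 5 without PNB-028 replicate 3). The NF-kappaB shift of 0.609 ranged from 0.198 to 0.931 with 1 array left out, the neutrophil shift of 0.57 from 0.235 to 0.865 and the endothelial shift of 0.241 from 0.19 to 0.281; the first 2 lost their call without PNB-028 replicate 1, and all 3 lost it with an estimated correlation (adjusted p 0.987) and with fry (0.98), at unchanged shifts. The median fold change ranged from -0.0233 to -0.00167.

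Directions turned for fibroblast genes (-0.0445 with array weights, -0.098 to 0.57 with 1 array left out, lowest without vehicle replicate 3), mitotic genes (-0.0427 to 0.00321, highest without vehicle replicate 1), hypoxia genes (-0.0944 to 0.244, lowest without PNB-028 replicate 2; -0.019 with the array width covariate), mast cell markers (-0.0813 to 0.665, lowest without vehicle replicate 3), Mertk (0.0656 with the mean of its probe sets) and Cck (-0.0975 with array weights, -0.128 without vehicle replicate 2, and -0.207 without PNB-028 replicate 3 to 0.223 without PNB-028 replicate 1); the cause was not tested. Tumours with the same replicate number did not deviate together (r of -0.0881, -0.0363 and 0.0826), and those with different numbers ran from -0.219 to 0.276. No pairing by number was seen, but 3 pairs cannot exclude a weak one. With the number as a replicate block, 0 genes and 3 lists were called. Signal over background could not be assessed from the deposited values.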

Other observations

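The tests in this part were set down only after the results they bear on had been seen.

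Host stroma varied between tumours. Fibroblast and matrix genes scored -0.81 in vehicle replicate 3 and -0.52 in PNB-028 replicate 2, against 0.18 to 0.58 in the other 4 tumours, and differed by 0.25 between the groups, whose SDs were 0.60 and 0.58 (27 members, camera, adjusted p = 0.11). The proteoglycan Dcn read 7.73 and 8.95 in those tumours and 10.69 to 11.86 in the others, and the receptor Pdgfra differed by 0.85 ± 0.26 (SE) between the groups. Mast cell markers had the same lowest tumours, at -1.004 and -0.39, with the receptor Kit at 0.41, or 0.26 over its probe sets, and Hdc, which makes histamine, at 0.32, or 0.64 over its probe sets (9 members, camera, adjusted p = 0.22). Macrophage markers averaged 0.17 (23 members, camera, adjusted p = 0.0976), with Mpeg1 at 0.31 and Marco at -0.39, although 4 of the 6 probe sets of Marco were higher (mean -0.08), and were also lowest in PNB-028 replicate 2 (-0.36) and vehicle replicate 3 (-0.23). With 1 array left out, the fibroblast mean ran from -0.098 without vehicle replicate 3 to 0.57 without PNB-028 replicate 2, the macrophage mean from 0.0233 without PNB-028 replicate 3 to 0.393 without PNB-028 replicate 2, and the mast cell mean from -0.0813 without vehicle replicate 3 to 0.665 without vehicle replicate 2. Single genes moved likewise, with Dcn at 0.11, Mpeg1 at 0.15 and Kit at 0.24 without vehicle replicate 3 and at 2.06, 0.47 and 0.68 without PNB-028 replicate 2, Kit at 0.13 without PNB-028 replicate 3 and Hdc at 0.063 without PNB-028 replicate 1. With the preset correlation fibroblast genes passed in camera without vehicle replicate 1 (0.436, adjusted p = 0.00111), vehicle replicate 2 (0.401, 0.00976) and PNB-028 replicate 2 (0.57, 3.34e-07). Macrophage markers passed without PNB-028 replicate 2 (camera, adjusted p = 4.07e-08) and vehicle replicate 2 (0.0262), and with all probe sets (2.88e-06), their mean (0.00319) and the stricter filter (0.0371). Mast cell markers passed without vehicle replicate 2 (camera, adjusted p = 0.0192) and PNB-028 replicate 2 (0.0231), and with all probe sets (0.00115). With an estimated correlation the adjusted p was 0.987 for each of the 3 lists. Endothelial scores followed these in part: vehicle replicate 3 was lowest (-0.20) and PNB-028 replicate 3, highest for all 3 stromal lists, was highest (0.22), while PNB-028 replicate 2 was at 0.05, above every vehicle tumour.

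The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real comparison gave 0 genes past adjustment in limma, and so did all 10 splits (highest other 0); 4 of 10 gave at least its 895 genes at unadjusted p under 0.05 (highest other 2268), and all 10 called at least its 3 lists (highest other 16). Of the 3 called lists, NF-kappaB had an adjusted p in camera of 6.95e-05 in the real split and down to 8.77e-08 in others, neutrophils 0.000178 and down to 2.54e-06, and endothelium 0.000149 and down to 0.0107; these lists were picked by their call in the real split.

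The NF-kappaB and neutrophil shifts were 0.609 and 0.57 and became 0.198 and 0.235 without PNB-028 replicate 1, so that 1 tumour carries most of both. The NF-kappaB list deviated in PNB-028 replicate 1 by 1.35, at the 100th percentile of 10000 random lists matched on expression, whose highest was 0.395. Thus genes of like expression did not share the shift, and the median of all genes deviated by -0.01. Whether that array or that tumour differs cannot be decided this way. The list was picked for a shift that this tumour carries, and its genes vary together (estimated correlation 0.52), unlike random ones. Of the neutrophil markers, S100a9 read 10.06 in PNB-028 replicate 1 and 5.09 to 7.66 in the others, and Retnlg 8.91 there and 6.62 to 8.09 in the others. Csf3r (10.58) and Cxcr2 (9.89) were also highest there. Il1r2 was not, at 9.60 there and 9.64 in PNB-028 replicate 2. Ly6g did not stand out either, at 12.44 there and 12.07 to 12.47 in the others, but it read high in every tumour. Of the 17 markers, 2 stand in another list. More neutrophil RNA in that tumour stays open, since both lists were picked for a shift that this tumour carries, and so does an effect of PNB-028.

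Single probe sets stood apart in several arrays. Higher by at least 1.5 (log2) than in each other array were 91 probe sets above the filter in PNB-028 replicate 1, and 1 to 14 in each of the others. Lower by at least 1.5 than in each other array were 186 in PNB-028 replicate 2 alone, 73 in replicate 1 and 79 in replicate 3. Among vehicle arrays, 213 were lower in replicate 3, 11 in replicate 1 and 12 in replicate 2. The other probe sets of the same genes differed by medians of 0.018 and -0.006 in PNB-028 replicates 2 and 1, and of -0.236 and -0.226 in PNB-028 replicate 3 and vehicle replicate 3. PNB-028 replicates 1 and 2 shared 45 such probe sets, and 0 were higher there; of the 14 other pairs, vehicle replicate 3 with PNB-028 replicate 2, the tumours low in stroma, had 64, and no other pair over 8. Of the 45, 1 stood for its gene in the comparison of the groups, Nr1h3, which read 12.40, 12.55 and 12.58 with vehicle and 8.71, 9.22 and 12.56 with PNB-028. For the pair, lower expression of the whole genes is argued against: the 803 other probe sets of the same 43 genes differed by a median of 0.03, against -1.08 for the 349 others of the 32 genes in the stroma-low pair. In limma's diffSplice, a test of probe sets against the rest of their gene, 266 genes passed at 0.05 in the real comparison. At least as many passed in 2 of 10 splits, the real one included (highest other 971). Of the 336 probe sets called in the real comparison, 38 were among these 45, and so were 8 of the 10 of smallest p. This is in part built in, since the 45 were chosen for low values in PNB-028 replicates 1 and 2. A defect of the probe sets or arrays, a sequence difference between sublines of the tumour and skipped exons all stay open and untested.

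One split, picked for the highest count of the 10, may reflect a structure of the samples other than treatment. That count was not tested against chance, and 0 genes passed adjustment in this split. Vehicle replicates 1 and 3 with PNB-028 replicate 3, against the other 3 arrays, gave 2268 genes at unadjusted p under 0.05, where the real comparison gave 895, and 971 genes in diffSplice. The arrays of the first set had interquartile widths of 3.79 to 3.82 and the others 3.88 to 3.90. Width alone is argued against, since the split gave 2542 such genes after quantile normalization, against 832 in the real comparison. Before that normalization the share was 19.3% among the 5911 dimmest genes, 15.5% among the 5910 between and 3.59% among the 5911 brightest. Of the 1140 dim genes, 936 were lower in the second set, but the share was nearly as high at middle levels. Quantile normalization also evens out an array-wide offset of dim values, so such an offset alone is argued against too. Enterocyte, secretory and CCK and gastrin scores also separated by this split, while junction and keratin scores did not. Whether another difference in background signal or a difference between the tumours underlies the split was not decided. The labels give no batch. With the array width as a covariate, PNB-028 gave 0 genes past adjustment, 1102 at unadjusted p under 0.05 and 3 called lists.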
